A study of Mus musculus with 18 samples.

How the data were processed

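RNA sequencing of whole epididymal white adipose tissue was described for 18 samples of male C57BL/6 mice, in 3 groups by the injected zygote (negative control, let-7d, let-7e). By the labels, 1 ug of total RNA, taken up in TRI reagent, went into each library and sequencing was on an Illumina NovaSeq. The deposited counts are whole-number read counts per Ensembl gene; per the labels the authors aligned with STAR to GRCm38.p6, with no version stated, and the tool that counted reads is not named. The authors kept genes by a filter on CPM whose threshold is not stated. A second deposited table, which the authors name as RPKM, holds values that are not comparable between genes or libraries: the gene lengths they imply repeat every 55487 cells down the columns of 16452 genes (100% of 222733 cells compared lay within 1%). It was not used here beyond that check, so its values are not reported in any unit. The count table gave 17 libraries, 5 of controls; control replicate 5 is not analysed here.

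Gene symbols, positions, transcript lengths and GC content came from GENCODE M21 (GRCm38); 16432 gene identifiers had a symbol and 20 had none. The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts were scaled with TMM, filterByExpr removed 0 genes, and edgeR's quasi-likelihood test was fitted to all 17 libraries with the group and the identifier series (4 early, 13 late) as terms; the common biological coefficient of variation was 0.36. The p-values, which are two-sided, were adjusted by the Benjamini-Hochberg method over the 16452 genes of a comparison, with a threshold of 0.05. DESeq2 gave no adjusted p to 617 genes in the comparisons with the controls and to 4237 in let-7e against let-7d, so its calls are adjusted over fewer genes. The 4 contrasts were let-7d against control, let-7e against control, let-7e against let-7d, and the mean of the injected groups against control; early against late is the coefficient of the series term. Groups, comparisons, tests, gene lists and alternatives were chosen before the data were examined, on the assumption of 18 libraries; the planned division of the controls into equal parts became 3 and 2. Levels are CPM with TMM scaling, and log2 CPM has a prior count of 2. Group means and SDs are over all libraries of a group, whereas fold changes account for the series. Total counts of 12717365 to 28972306 per library set the counting precision.

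Named genes followed a rule: per comparison, since none passed, the 3 with the smallest unadjusted p in each direction among genes with a mean of at least 1 CPM and a symbol that is not a predicted gene, pseudogene or receptor segment, and 18 genes fixed in advance, of which 16 were measured. Examples of list members, DESeq2 calls and marker transcripts were chosen after their values were seen, mostly by smallest p. The genes named for early against late were also chosen after their values were seen.

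The 40 gene lists came from textbook knowledge, and the 39 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and with camera at an estimated correlation and fry. A count adjusted over the list alone uses only the p-values of its members. Lists of neighbouring organs and of nuclear noncoding RNAs were added after the data were seen. The level of a list in a library is the mean log2 CPM of its members. These levels were compared by exact permutation within the late libraries (126 arrangements, smallest possible p 0.00794). The smallest adjusted p over the lists was 0.635, with let-7e. It was shared by the granulocyte and mast cell (exact p = 0.0476), endothelial (0.0556), insulin signalling (0.0635) and extracellular matrix lists (0.0635).

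The pipeline was tested on simulated data in which 100 genes at 2-fold and 100 at 4-fold were planted: it recovered 58% and 77% of them in the design of let-7d against control, 60% and 81% for let-7e, and 56% and 88% for let-7e against let-7d, with 5, 4 and 8 false calls. Libraries were compared in pairs for duplicates within groups; the closest pair, let-7d 3 and let-7d 6, had a chi-square per degree of freedom of 14.65, far over 1. Alternatives were DESeq2 size factors, a filter at 5 CPM on average, the DESeq2 Wald test, limma-voom with quality weights, the replicate number as a block with and without the series term, no series term, late libraries only, only the groups compared, a threshold of 0.1, and each library left out in turn. Chosen after the data were seen were fits without the 4 libraries that hold transcripts abundant in neighbouring organs or epithelium and fits with each library's trend with transcript length and GC content taken out.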

Results

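Transcript levels were measured by RNA sequencing of whole epididymal white adipose tissue (eWAT) from male C57BL/6 mice. By the labels the mice are of a generation called Fm, sired from zygotes that had been microinjected with miR-let-7d, miR-let-7e or a negative control; let-7 is a family of microRNAs, which lower the level or translation of messenger RNAs that carry their seed matches. The title of the series places the question in paternal mitochondrial dysfunction and the inheritance of a decline in metabolism. The mice ate chow from weaning to week 6 and the diet labelled LFD from then to week 15, while the age label gives 24 weeks; the labels do not settle which age holds. The 17 libraries analysed fall into 5 control, 6 let-7d and 6 let-7e libraries. The labels also describe a control replicate 5, which is not analysed here. Total counts ran from 12717365 (let-7d 6) to 28972306 (let-7d 1) per library over 16452 genes. The controls held 20603723 (control 1), 20642717 (control 2), 28523424 (control 3), 15324887 (control 4) and 23455160 counts (control 6). The other let-7d libraries held 21692312, 23144804, 14621333 and 15216079 counts for replicates 2 to 5. The let-7e libraries held 22620047, 28245324, 18041067, 17147025, 23677964 and 15913478 counts for replicates 1 to 6. Library identifiers form an early series (let-7d 1 and 2, let-7e 1 and 2) and a late series (the other 13), and no control is of the early series.

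Transcripts abundant in the organs beside this fat pad, or in epithelium, stood high in 4 libraries. Control 3 held Akr1b7, an aldo-keto reductase abundant in the vas deferens, at 14040 CPM (counts-per-million, TMM-scaled), Crisp1, a secretory protein of the epididymis, at 2927 CPM, and the smooth muscle genes Myh11 at 5203 CPM and Actg2 at 1477 CPM. Control 6 held the spermatid genes Prm2, a protamine, at 331.3 CPM and Tnp2, a transition protein, at 203.9 CPM, and the germ cell lactate dehydrogenase Ldhc at 281.8 CPM. The let-7d 1 library held Cdh16 and Cldn2, made by absorptive epithelium, at 96.06 and 149 CPM and Foxj1, the regulator of motile cilia, at 49.36 CPM. In let-7d 5 the same genes stood at 33.76, 43.5 and 59.1 CPM. Let-7e 1 held a lower level of Akr1b7 at 17.28 CPM and of Cldn2 at 9.611 CPM. The epithelial genes Epcam, Krt8 and Cldn7 stood at 12.95, 20.66 and 6.077 CPM in let-7d 3 and at 6.701, 10.1 and 2.204 CPM in let-7e 1, 2 libraries that the setting without 4 libraries keeps. The first principal component of log2 CPM, with 29.1% of the variance, set control 3, control 6, let-7d 1 and let-7d 5 apart from the rest.

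**Figure D1:**
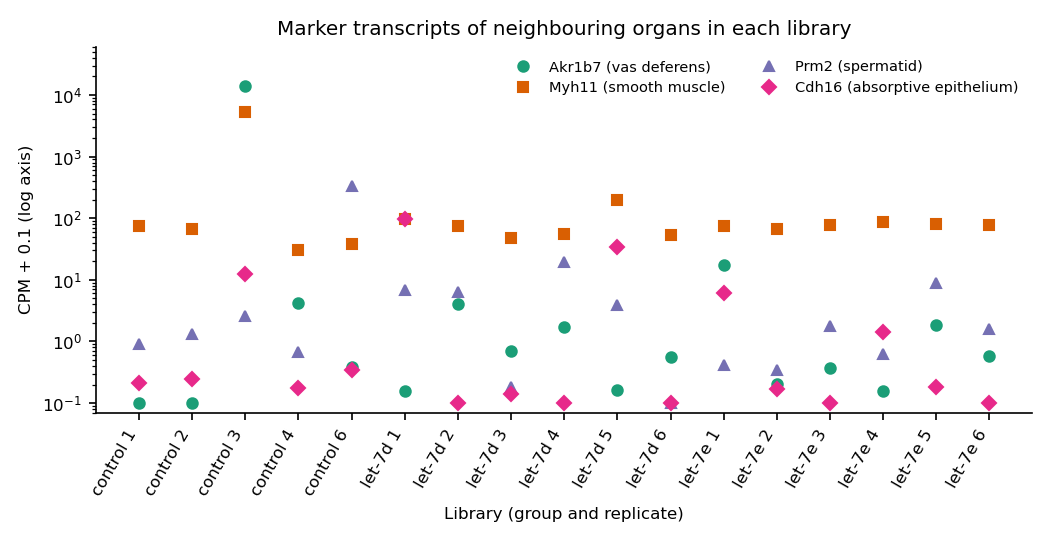
Level of 4 marker transcripts in each of the 17 libraries, in CPM plus 0.1 on a log axis, with libraries by group and replicate on the horizontal axis and 1 symbol per gene. Akr1b7 and Myh11 stand highest in control 3, Prm2 in control 6, and Cdh16 in let-7d 1 and let-7d 5.

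Let-7d against control asks which transcripts of the fat of Fm males differ when the zygote received let-7d. Pdgfc, a growth factor of the platelet-derived family, stood at 30.8 ± 5.68 CPM (SD, n = 6) in let-7d libraries and 18.7 ± 2.84 CPM (SD, n = 5) in controls. Axin2, a feedback inhibitor and readout of Wnt signalling, stood at 29.6 ± 9.15 CPM against 13.4 ± 2.65 CPM. Lower in let-7d were Tbx3, a T-box transcription factor, at 17.4 ± 3.96 against 49.5 ± 21.7 CPM, and Cxcl12, a chemokine made by stromal cells, at 136 ± 19.3 against 207 ± 29.8 CPM. For each of these 4 genes the 6 let-7d libraries lay wholly to 1 side of the 5 controls, as they did for 85 genes (0.517%), where chance gives 0.433%. None of them passed the correction over all genes: with the identifier series as a term, the log2 fold changes were 0.61 (SE 0.117) for Pdgfc, 1.08 (SE 0.211) for Axin2, -1.30 (SE 0.286) for Tbx3 and -0.49 (SE 0.111) for Cxcl12, each at an edgeR adjusted p of 0.46. The rule for named genes also gave Ckmt1, a mitochondrial creatine kinase, with a log2 fold change of 3.56 (SE 0.848), falling to 1.83 without let-7d 3, where it stood at 12.7 CPM. It also gave Ptgs2, a prostaglandin synthase, with -8.61 (SE 2.1), which stood at 1116 CPM in control 3 and gave -0.11 without that library. Pdgfc spans bases 81036416 to 81214040 of chromosome 3 (GRCm38, ENSMUSG00000028019.9), Axin2 108920349 to 108950783 of chromosome 11 (ENSMUSG00000000142.15), Tbx3 119670669 to 119684724 of chromosome 5 (ENSMUSG00000018604.18) and Cxcl12 117168535 to 117181367 of chromosome 6 (ENSMUSG00000061353.11).

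With let-7d the count of genes past an adjusted p of 0.05 was 0 of 16452 by edgeR, with 1676 (10.2%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.46. DESeq2 called 10 genes, 7 higher and 3 lower, and limma-voom called 0. The genes DESeq2 called lower were Tbx3, Cxcl12 and Vash2, and those it called higher included Pdgfc (0.62), Axin2 (1.09) and the epithelial genes Vil1 (3.75), Hnf4a (5.04) and Cdhr5 (6.12). Of the 10, 6 had their highest level in let-7d 1 or let-7d 5 and 3 in control 3 or control 6. Without those 4 libraries edgeR called 0, with 1285 at an unadjusted p under 0.05, a setting added after the data were seen. The unadjusted count was 2718 without control 2, 1048 without let-7d 3 and 962 with only the groups compared, and 38 of 100 splits, the real one included, gave at least the 1676.

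Of the genes fixed in advance for this study, Lep, which encodes the satiety hormone leptin, stood at 1943 ± 678 CPM (SD, n = 6) with let-7d against 822 ± 738 CPM (SD, n = 5), above the control mean of log2 CPM in 6 of 6 libraries, with a log2 fold change of 1.10 (SE 0.513; adjusted p = 0.489). It lay between 1753 and 2546 CPM in 5 let-7d libraries and at 660.3 CPM in let-7d 5, while 4 controls lay between 248.3 and 801.7 CPM and control 2 at 2080 CPM. Without control 2 its log2 fold change was 1.80. Fasn, fatty acid synthase, had -0.72 (SE 0.499) with controls 1 and 4 at 33490 and 20720 CPM, and gave -0.10 without control 1. Scd1, a fatty acid desaturase, had -0.52, or -0.24 without control 1, and Cpt1b, which admits fatty acids to mitochondria, -1.10, or -0.47 without control 6. Cpt1b was near the floor, with means of 0.867 CPM in controls and 0.491 CPM with let-7d. Dicer1, which cuts microRNAs from their precursors, had -0.13 (SE 0.0876; adjusted p = 0.602), or -0.06 without control 3, Insr, the insulin receptor, -0.14, and Adipoq, which encodes adiponectin, -0.31, or -0.19 without control 4. Pparg, the master regulator of fat cells, had 0.19 (0.08 without let-7d 6 and 0.29 without control 1), Ppargc1a, a regulator of mitochondrial biogenesis, 0.30 (0.14 without let-7d 1), and Tfam, which packs mitochondrial DNA, -0.15 (-0.07 without control 6). The sign of Ppargc1a turned without the 4 libraries that held transcripts abundant in neighbouring organs or epithelium (-0.09). The mitochondrial transcript mt-Co1 had -0.37 (-0.16 without control 1) and Ndufs1, a subunit of respiratory complex I, -0.18 (-0.04 without control 1). None of the 16 measured passed, and Ucp1 and Hmga2 were not measured.

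**Figure D2:**
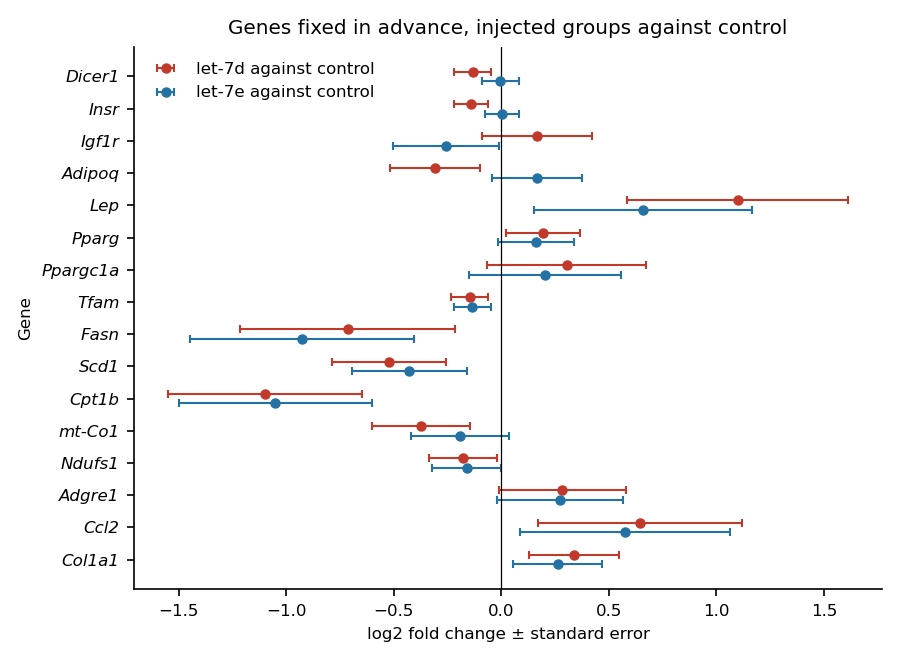
Log2 fold change with its standard error for the 16 measured genes fixed in advance, let-7d (red) and let-7e (blue) against control. Lep lies at 1.10 and 0.66 and Fasn at -0.72 and -0.93; no gene passed the adjusted threshold in either comparison, and the sign of Dicer1 in let-7e against control turns with DESeq2 size factors.

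**Figure D3:**
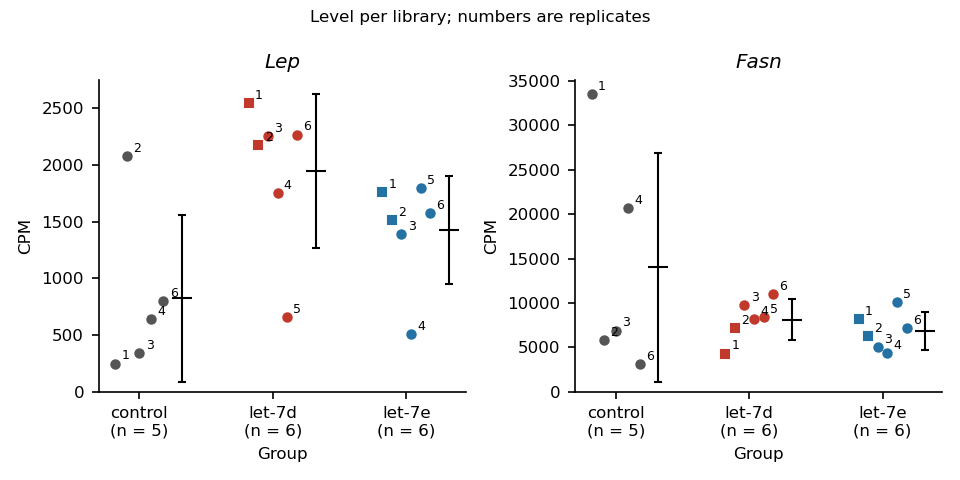
Level of Lep (left) and Fasn (right) in CPM in each library, by group, with replicate numbers beside the points, squares for the early identifier series and circles for the late, and a bar at the mean ± SD. Control 2 lies at 2080 CPM of Lep among controls otherwise at 801.7 CPM or below, and controls 1 and 4 hold the highest Fasn at 33490 and 20720 CPM.

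By gene list, 9 of 39 tested lists were called with let-7d by camera with its preset correlation, 5 higher and 4 lower. All 9 calls were lost with an estimated correlation, each at an adjusted p = 0.967, and the smallest adjusted p by fry was 0.852. The number called was 19 without the 4 libraries and 5 with the replicate block. Genes of the extracellular matrix were higher in 23 of 28 (median log2 fold change 0.28, adjusted p = 9.75e-08), among them the collagens Col5a1 (0.61), Col6a2 (0.74) and Col3a1 (0.43), and the list level lay above the control mean in 6 of 6 libraries, at 8.42 in let-7d 3 and 7.74 to 7.96 in the others. Macrophage markers were higher in 18 of 22 (median 0.23, adjusted p = 0.00366), with Cx3cr1 at 0.78 and Mrc1 at 0.36, and cell cycle genes in 19 of 26 (median 0.23, adjusted p = 0.0191), with Mki67 at 0.94. Proteins of the cytosolic ribosome were higher in 65 of 73 (median 0.08, adjusted p = 2.17e-05) and endothelial markers in 14 of 17 (median 0.13, adjusted p = 0.0191). The plain list levels of both lay below the control mean in most let-7d libraries, 4 of 6 for the ribosome and 5 of 6 for the endothelial list. Without the 4 libraries with transcripts abundant in neighbouring organs or epithelium the endothelial list turned to lower (adjusted p = 0.243). Genes of fatty acid oxidation were lower in 20 of 22 (median -0.19, adjusted p = 0.0118), with Ehhadh at -0.76. Nuclear subunits of complex I were lower in 32 of 36 (median -0.12, adjusted p = 0.0191), messenger RNAs of the mitochondrial genome in 8 of 8 (median -0.32, adjusted p = 0.0234), and antioxidant genes in 18 of 24 (median -0.12, adjusted p = 0.0232), with Gpx4 at -0.64 and Sod1 at -0.39. Complex I turned to higher with the replicate block (adjusted p = 0.826). Among late libraries the level of complex I differed from control by -0.0491 (exact permutation p = 0.778). That of the mitochondrial messenger RNAs differed by -0.234 (exact permutation p = 0.437). Not 1 member of these 9 lists passed adjusted over all genes or adjusted over the list alone.

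Lists of interest that were not called with let-7d include the transcripts with conserved let-7 sites, lower in 34 of 46 (median -0.14, adjusted p = 0.186). Their level was 5.16 in control 6 and 4.70 to 4.80 in the other controls, a range that holds the late let-7d mean of 4.73. Not called either were the proteins of microRNA processing, lower in 12 of 19 (median -0.02, adjusted p = 0.862). Markers of epididymis and testis were lower in 9 of 10 (median -3.02, adjusted p = 0.186), with 2 passing adjusted over the list alone, Spink8 (-9.80) and Crisp1 (-11.16), both high in control 3. The inflammation, thermogenic and lymphocyte lists each had 1 member passing adjusted over the list alone, Cxcl12, Ckmt1 and the T cell regulator Gata3 (-4.43). Smooth muscle genes had 3 passing adjusted over the list alone, Cnn1 (-5.49), Des (-2.87) and Myh11 (-3.59). In control 3 this list stood at 8.18 on the log2 CPM scale, against 5.23 to 5.90 in the other controls.

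Let-7e against control asks the same of let-7e. Zeb2, a zinc finger repressor with a part in mesenchymal cell fate, stood at 169 ± 52.3 CPM (SD, n = 6) with let-7e and 94.6 ± 19.5 CPM (SD, n = 5) in controls, above the control mean in 6 of 6 libraries. With let-7d it stood at 165 ± 43.6 CPM (SD, n = 6), so its level is not particular to let-7e. It was highest in let-7e 2, of the early series, which holds no control, and these plain means do not account for the series. Cdc42ep2, which binds the small GTPase Cdc42, and Syde1 were also among the 3 higher genes of smallest p, with log2 fold changes of 0.54 (SE 0.142) and 0.40 (SE 0.114) against 0.58 (SE 0.161) for Zeb2. The lower genes of smallest p were Efna3, an ephrin ligand (-3.27, SE 0.745), Lmntd2, a lamin tail domain protein (-5.19, SE 1.21), and Ttc25, a protein of motile cilia (-2.998, SE 0.7). Each of the 6 had an edgeR adjusted p of 0.366, which misses the threshold. Efna3 gave -1.53 without control 3, and its level there was 3.51 on the log2 CPM scale against 0.49 or lower in the other controls. Lmntd2 gave -3.76 and Ttc25 -2.32 without control 6, the library with spermatid transcripts. Zeb2 spans bases 44983632 to 45117395 of chromosome 2 (ENSMUSG00000026872.18), and Cdc42ep2 spans 5915636 to 5924816 of chromosome 19 (ENSMUSG00000045664.5).

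With let-7e the count of genes past an adjusted p of 0.05 was 0 of 16452 by edgeR, with 1725 (10.5%) at an unadjusted p under 0.05. DESeq2 called 15 genes, all 15 lower with let-7e, of which 13 had their highest level in control 3 or control 6, and limma-voom called 0. Without the 4 libraries with transcripts abundant in neighbouring organs or epithelium edgeR called 0, with 1117 at an unadjusted p under 0.05. The unadjusted count was 2730 without control 2 and 911 with only the groups compared, and 27 of 100 splits gave at least the 1725. Of the genes fixed in advance, Lep had a log2 fold change of 0.66 (SE 0.507; adjusted p = 0.667; 1423 ± 476 CPM), or 1.36 without control 2 and 0.44 without control 1, and Fasn had -0.93 (6861 ± 2114 CPM), or -0.31 without control 1. Dicer1 had -0.00 (adjusted p = 0.991) and its sign turned with DESeq2 size factors. Adipoq had 0.16 and Pparg 0.16, and both turned sign without the 4 libraries, to -0.02 and -0.05, and were 0.05 each without control 3. The sign of mt-Co1 (-0.19) turned without control 1, to 0.02.

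By gene list, 18 of 39 were called with let-7e, 10 higher and 8 lower, a number that was 27 without the 4 libraries and 10 with the replicate block. Extracellular matrix genes were higher in 25 of 28 (median 0.45, adjusted p = 6.46e-15; 0.282 as the adjusted p with an estimated correlation), with Col3a1 at 0.59, Col5a2 at 0.61 and Col4a2 at 0.43. Endothelial markers were higher in 16 of 17 (median 0.31, adjusted p = 1.18e-11; 0.242 as the adjusted p with an estimated correlation), with the junction genes Cdh5 at 0.45 and Cldn5 at 0.50 and the receptor Tie1 at 0.37. Both list levels lay above the control mean in 5 of 6 libraries. Adipocyte genes were higher in 15 of 18 (median 0.18, adjusted p = 0.000413), with the adrenergic receptor Adrb3 at 0.42, and genes of lipolysis and lipid uptake in 13 of 20 (median 0.20, adjusted p = 0.00191), each at an adjusted p = 0.717 with an estimated correlation. Without the 4 libraries both turned to lower, at adjusted p = 0.881 and 0.248, and the lipolysis level was 9.72 in let-7e 6 against 9.28 to 9.43 in the other let-7e libraries. The enzymes and regulators of cholesterol synthesis were lower in 21 of 22 (median -0.39, adjusted p = 0.000272; 0.717 as the adjusted p with an estimated correlation), with Cyp51 at -1.25 and Sqle at -0.76. Genes of lipogenesis were lower in 17 of 20 (median -0.48, adjusted p = 0.0325; 0.771 as the adjusted p with an estimated correlation), with Elovl6 at -2.32 and Acly at -1.28. Controls 1 and 4 held Elovl6 at 706.8 and 349.4 CPM and Acly at 3853 and 1832 CPM, while the other controls, at 21.93 to 98.59 and 283.7 to 758.3 CPM, overlapped the let-7e libraries, and with the replicate block the list turned to higher (adjusted p = 0.672).

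Proteins of the cytosolic ribosome were lower in 63 of 73 with let-7e (median -0.08, adjusted p = 0.00146), subunits of complex IV in 13 of 13 (median -0.15, adjusted p = 0.0332) and of complex I in 33 of 36 (median -0.11, adjusted p = 0.0285). With an estimated correlation the adjusted p was 0.771 for the ribosome and complex IV and 0.839 for complex I. With the replicate block complex IV and complex I turned to higher, at adjusted p = 0.984 and 0.672. Lymphocyte markers were lower in 24 of 28 (median -0.67, adjusted p = 0.00347; 0.717 as the adjusted p with an estimated correlation), with Trac of T cells at -1.84 and Igkc of B cells at -2.11, and among the controls control 6 held the highest lymphocyte level. Markers of granulocytes and mast cells were lower in 8 of 10 (median -0.59, adjusted p = 0.02; 0.379 as the adjusted p with an estimated correlation), with the mast cell proteases Cma1 at -0.91 and Cpa3 at -0.67. Markers of epididymis and testis were lower in 9 of 10 (median -4.74, adjusted p = 0.0122; 0.717 as the adjusted p with an estimated correlation), beside the levels in control 3 and control 6. Of them 9 passed adjusted over the list alone and 0 over all genes, and the call was lost and its direction turned without the 4 libraries (adjusted p = 0.56). In the other 17 called lists 0 members passed adjusted over the list alone. Cell cycle, insulin signalling, immediate early, inflammation, progenitor and stress response lists were also called higher, with medians of 0.05 to 0.23, and all were lost with an estimated correlation, the smallest adjusted p among them being 0.384 for insulin signalling. Transcripts with conserved let-7 sites were not called (adjusted p = 0.314), with a test direction of higher beside a median of -0.02, but were called higher without the 4 libraries (adjusted p = 0.0335) and without the series term (adjusted p = 0.0236). Proteins of microRNA processing were not called (adjusted p = 0.792; median -0.00), but were without the series term (adjusted p = 0.0375). Smooth muscle genes had 5 passing adjusted over the list alone, 4 of them lower and high in control 3 (Cnn1, Des, Myh11 and Tagln) and 1 higher, the adhesion molecule Mcam (0.55).

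**Figure D4:**
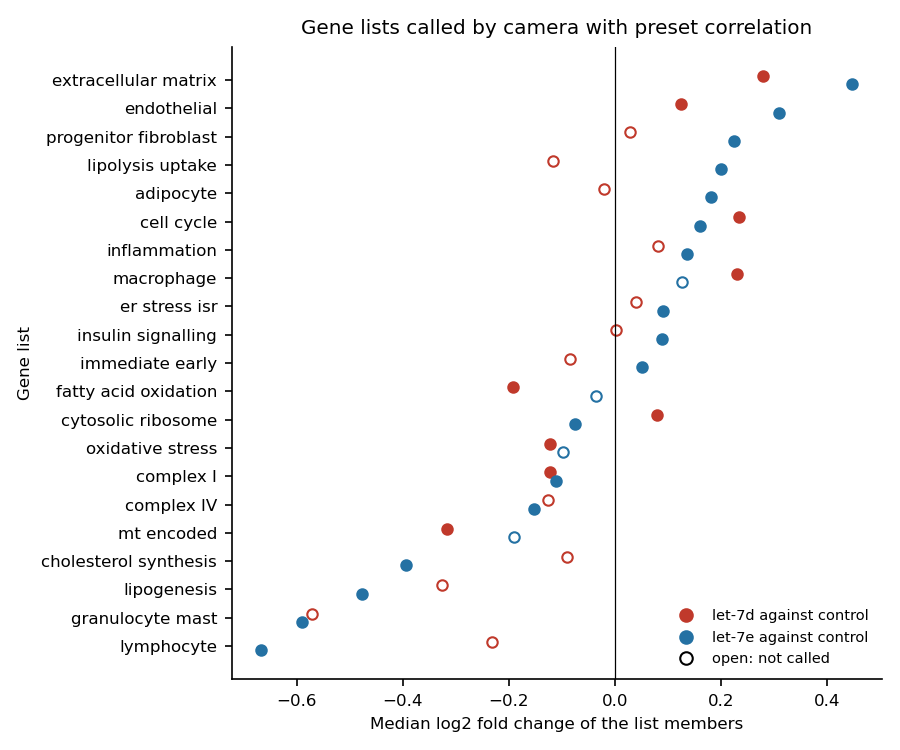
Median log2 fold change of the members of each list called in at least 1 comparison with the controls, let-7d in red and let-7e in blue; filled points were called by camera with the preset correlation and open points were not. Extracellular matrix lies highest with let-7e at 0.45 and the lymphocyte list lowest at -0.67; no call held with an estimated correlation, and the list of epididymis and testis markers (median -4.74 with let-7e) is left out for scale.

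Let-7e against let-7d tests the difference between the 2 microRNAs, with equal numbers of early and late libraries on both sides. Adcy5, an adenylyl cyclase, stood at 358 ± 105 CPM with let-7e and 206 ± 33.4 CPM with let-7d (SD, n = 6 each), a log2 fold change of 0.78 (SE 0.163), with 6 of 6 let-7e libraries above the let-7d mean. Ncor1, a nuclear receptor corepressor, had 0.35 (SE 0.0752) and Pdzrn3, a ubiquitin ligase, 0.56 (SE 0.121). Arrdc2, an arrestin domain protein, had -0.71 (SE 0.145) with no overlap between the groups (chance gives this in 0.216% of genes, and 0.237% showed it), Acsl3, which activates fatty acids, -0.73 (SE 0.191), and Pdgfc -0.41 (SE 0.105). Each had an edgeR adjusted p of 0.705, and 0 genes were called, with 1095 (6.66%) at an unadjusted p under 0.05, or 621 without let-7d 1 and 694 without let-7e 2. Of 100 splits 10 gave at least as many at an unadjusted p under 0.05. DESeq2 called 14, 11 higher and 3 lower, among them Adcy5, Ncor1, Pdzrn3 and Arrdc2, and limma-voom called 0; without the 4 libraries edgeR called 0, with 1408 at an unadjusted p under 0.05. Adcy5 spans bases 35154877 to 35305738 of chromosome 16 (ENSMUSG00000022840.9), Ncor1 62316426 to 62458541 of chromosome 11 (ENSMUSG00000018501.17) and Arrdc2 70835129 to 70839720 of chromosome 8 (ENSMUSG00000002910.11).

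Between the 2 microRNAs 10 of 39 lists were called, 7 higher and 3 lower with let-7e, or 15 with late libraries only. The cytosolic ribosome was lower in 73 of 73 (median -0.16, adjusted p = 5.75e-23; 0.638 as the adjusted p with an estimated correlation), with Rps21 at -0.29 and Rps13 at -0.27, and its level was highest in let-7d 4. Genes of lipolysis were higher in 17 of 20 (median 0.28, adjusted p = 2.25e-07), with the triglyceride lipase Pnpla2 at 0.52 and the adrenergic receptor Adrb1 at 0.71, and adipocyte genes in 13 of 18 (median 0.32, adjusted p = 2.78e-05), with Adipoq at 0.47. Endothelial markers were higher in 14 of 17 (median 0.15, adjusted p = 6.84e-06), with the receptor Kdr at 0.45, and cholesterol synthesis was lower in 22 of 22 (median -0.34, adjusted p = 6.84e-06). For these 4 lists the adjusted p with an estimated correlation was 0.638. Fatty acid oxidation was higher in 22 of 22 (median 0.16, adjusted p = 0.000245; 0.756 as the adjusted p with an estimated correlation). Transcripts with conserved let-7 sites were higher in 30 of 46 (median 0.08, adjusted p = 0.00213; 0.638 as the adjusted p with an estimated correlation), with the insulin receptor substrate Irs2 at 0.67 and Igf2bp2 at 0.57. Immediate early genes were higher in 19 of 24 (median 0.18, adjusted p = 0.00217), extracellular matrix genes in 19 of 28 (median 0.09, adjusted p = 0.0394), and lymphocyte markers lower in 25 of 28 (median -0.37, adjusted p = 0.00439), with adjusted p of 0.726, 0.885 and 0.879 once the correlation was estimated. No member of the 10 called lists passed adjusted over the list alone. Insulin signalling was not called (adjusted p = 0.123), but 3 of its 25 members passed adjusted over the list alone and 0 over all genes: Irs2 (0.67), the kinase subunit Pik3ca (0.18) and the binding protein Igfbp3 (-0.52).

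The mean of both injected groups was set against control, a contrast that 1 group alone can carry. Extracellular matrix genes were higher in 25 of 28 (median 0.36, adjusted p = 3.41e-13) and endothelial markers in 16 of 17 (median 0.20, adjusted p = 5.34e-07), both at an adjusted p = 0.507 with an estimated correlation. Macrophage markers were higher in 16 of 22 (median 0.19, adjusted p = 0.011) and cell cycle genes in 19 of 26 (median 0.20, adjusted p = 0.011), and subunits of complex I lower in 33 of 36 (median -0.12, adjusted p = 0.0221). These 3 had an adjusted p = 0.93 with an estimated correlation, and no member of the 5 lists passed adjusted over the list alone. The number of lists called, 5 here, was 22 without the 4 libraries. The endothelial median was 0.31 with let-7e and 0.13 with let-7d, where 5 of 6 libraries lay below the control mean. EdgeR called 0 genes, with 1915 (11.6%) at an unadjusted p under 0.05, or 3049 without control 2, and 16 of 100 splits gave at least the 1915. DESeq2 called 24, 2 higher and 22 lower, of which 19 had their highest level in control 3 or control 6, and limma-voom called 0. Without the 4 libraries edgeR called 0, with 1120 at an unadjusted p under 0.05. Across genes, which are not independent replicates, the let-7d and let-7e fold changes correlated at r = 0.783 with a covariance of 0.403. Sharing the same controls gives a correlation by itself: 20 simulations with unchanged groups gave a mean r of 0.583 (0.556 to 0.619) and a mean covariance of 0.0997. The simulations drew each gene independently, so they do not carry transcripts that rise together in 1 control library. The controls were also divided, in fits of the late libraries only and without the series term. With let-7d against controls 1 to 3 and let-7e against controls 4 and 6, r was -0.01, and with the parts exchanged it was -0.06. The similarity thus did not hold with separate controls in those late libraries, a smaller set than the 1 that gave 0.783. The controls of those parts differ in their transcripts abundant in neighbouring organs or epithelium.

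The identifier series was compared within the same fit, early minus late. Malat1, a nuclear long noncoding RNA, rose by 2.06 on the log2 scale (SE 0.158, adjusted p = 2e-06), from 347 ± 73.1 CPM in 13 late libraries to 1405 ± 72.5 CPM in 4 early ones. Muc6, a mucin, rose by 1.42, and Zfpm1, a GATA cofactor, fell by 1.56 and Hic1, a zinc finger repressor, by 1.53. EdgeR called 2009 genes, 903 higher and 1106 lower in the early libraries. Genes of microRNA processing were called higher in 8 of 19 members and as a list (median 0.26, adjusted p = 2.14e-06; 0.0589 as the adjusted p with an estimated correlation), and endothelial markers lower in 7 of 17 and as a list (median -0.24, adjusted p = 2.14e-06; 0.488 as the adjusted p with an estimated correlation). Camera called 9 lists between the series, against a median of 14 and a highest of 24 in the other splits, so chance is not excluded for the lists. Each group comparison above has this term in its model, and none of the controls is of the early series.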

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

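Of the tests in this part, those on the genes lowest in the injected groups and on the spread of list levels, and those of the called lists without the 4 libraries with transcripts abundant in neighbouring organs or epithelium, were chosen after the result was seen. A sample far from the others of its group was found in 18 of 231 groups of values tested, where chance gives about 1 in 20.

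In controls, control 3 stood far above the others in the level of smooth muscle genes (8.18 against 5.23 to 5.90 log2 CPM), in Ptgs2 (10.12 against 0.02 or lower) and in Efna3 (3.51 against 0.49 or lower). Control 6 stood above the others in lymphocyte markers (1.96 against 0.72 to 0.89) and in transcripts with conserved let-7 sites (5.16 against 4.70 to 4.80). Control 1 stood above the others in erythroid markers (5.25 against 3.46 to 3.98) and in Acsl3 (5.08 against 4.09 to 4.30). Control 2 stood below the others in granulocyte and mast cell markers (1.52 against 1.92 to 2.07). Among let-7d libraries, let-7d 5 was highest in smooth muscle genes (6.48 against 5.40 to 5.74) and lowest in Lep (9.37 against 10.78 to 11.31). Let-7d 3 was highest in extracellular matrix genes (8.42), let-7d 4 in the cytosolic ribosome (7.48), let-7d 2 in Insr (7.01) and let-7d 1 in Igf1r (6.38). Among let-7e libraries, let-7e 4 was lowest in Lep (8.98 against 10.44 to 10.81), let-7e 6 was highest in lipolysis genes (9.72) and had the fewest genes detected (16303 against 16413 to 16423), and let-7e 1 was lowest in imprinted genes (4.24 against 4.43 to 4.50).

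The first pattern weighed is the set of 220 genes with a log2 fold change under -3 for the mean of the injected groups against control. Of these, control 6 held the highest level of 140 and control 3 of 74, and without both only 2 of the 220 remained under -3, while without any other pair of controls 80 to 220 did. The 220 were picked by fold change in these same libraries, so that drop restates where the highest levels lie and is not separate support. In 10.5% of the 220 the median control lay at least 2-fold over the median injected library. For this picked set, that argues against a lower level after injection as the source of folds under -3. It does not bear on other genes or on smaller changes. A candidate explanation is RNA of the vas deferens, epididymis or testis, which lie beside this fat pad, in control 3 and control 6, where Akr1b7 reached 14040 CPM and Prm2 331.3 CPM. Whether it entered at dissection or in handling was not tested.

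The second pattern is the difference between the identifier series, 2009 genes called, against at most 83 in the other 99 of 100 divisions of the let-7d and let-7e libraries. Only the real division, 1 of 100, gave as many, the smallest share that 100 divisions can show, so chance is unlikely as the source. The values argue against depth as the whole source, since 1631 of the 2009 stayed called with each library thinned to 12717365 counts. They also argue against transcripts abundant in neighbouring organs or epithelium as the whole source. Without the 4 libraries 1510 of the 2009 stayed called at an adjusted p under 0.05, and 2004 kept their direction at an unadjusted p under 0.05. A trend with GC content and length is a candidate explanation for much of it: genes called higher in the early libraries had a median GC of 44.6% and those called lower 57.4%, and 419 stayed called once each library's trend was taken out. The other calls ended because the folds shrank, the median absolute log2 fold change going from 0.48 to 0.27, while the SE went from 0.101 to 0.106. Malat1 went from 2.06 to 1.84 (SE 0.165, adjusted p = 2.95e-05), which argues against the trend as its whole source, and a difference between the mice of the series stays open, untested.

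The third pattern is the number of lists called by camera in the comparisons with the controls. Relabelled splits of the late libraries called a median of 16 lists in both comparisons, and no list was called with an estimated correlation, so members that vary together between mice may account for the calls. Against transcripts abundant in neighbouring organs or epithelium as the whole source, 21 of the 27 calls kept their direction and their call without the 4 libraries, where the number of lists called went from 9 to 19 for let-7d, 18 to 27 for let-7e and 5 to 22 for the mean. As many lists as called were reached in 85 of 100 splits for let-7d (9 lists, highest other 27), 43 for let-7e (18, highest other 27), 83 for let-7e against let-7d (10, highest other 23) and 94 for the mean (5, highest other 29), so chance cannot be excluded in any of them. An effect of the injected microRNA on these lists stays open.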

How the results depend on the processing

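The alternatives without the 4 libraries that hold transcripts abundant in neighbouring organs or epithelium (control 3, control 6, let-7d 1 and let-7d 5) and with the length and GC trend taken out were chosen after the result was seen; the others were planned. The count of genes called stayed 0 in all 4 comparisons with DESeq2 size factors, the filter at 5 CPM, limma-voom, no series term, late libraries only, the replicate block, a threshold of 0.1, both added alternatives and each library left out; with only the groups compared it stayed 0 in the 3 comparisons where that can be run. The replicate block gave 0 called genes in each comparison, with 1781, 1854, 845 and 1970 at an unadjusted p under 0.05 for let-7d, let-7e, let-7e against let-7d and the mean; same-numbered mice of different groups were not alike (16 pairs, median r -0.0262). The DESeq2 Wald test gave 10, 15, 14 and 24 genes, and the cause was not tested. The replicate block without the series term gave 1 for let-7d (Axin2, 1.15) and 3 for the mean, Axin2 and Zeb2 among them, named after their values were seen. Zeb2 for the mean had a log2 fold change of 0.86 there and 0.57 in the main fit. Since no control is of the early series, the calls of that block cannot be told apart from the series difference. Fits with limma-trend on the RPKM-named table were planned and not run, since its values are not comparable between libraries, and the planned fit with no filter moved nothing, since filterByExpr removes 0 genes.

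The correlation of let-7d and let-7e fold changes, 0.783, lay between 0.699 and 0.873 with each library left out, at 0.871 with the replicate block and at 0.663 without the 4 libraries, within its jackknife SD of 0.184 of the main value.

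Of the genes named, the direction turned in 32 of the 1386 values, none of which passed a test; the cause was not tested. With let-7d these were Igf1r (-0.0112, replicate block), Ppargc1a (-0.0942, without the 4 libraries) and Col1a1 (-0.0237, replicate block without the series term). With let-7e, Dicer1 (-0.00) turned with DESeq2 size factors (0.0046), the DESeq2 test (0.0042), no series term (0.0902), late libraries only (0.0196), the block without the series term (0.0758), only the groups compared (0.0384), without the 4 libraries (0.0465), and ranged from -0.0695 to 0.0652 with each library left out. Insr (0.00) turned with limma-voom (-0.0738), without the 4 libraries (-0.0391), and ranged from -0.0335 to 0.0418. Without the 4 libraries Igf1r gave 0.0886, Adipoq -0.0186 (-0.0607 with limma-voom) and Pparg -0.0478. mt-Co1 ranged from -0.335 (without let-7e 6) to 0.0225 (without control 1). Col1a1 gave -0.0831 with the block without the series term.

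Of the called or named lists, 139 values stood, 99 lost the call, 3 gained it and 11 turned direction; the cause was not tested. Turned with the replicate block, at the adjusted p given, were complex I with let-7d (0.826) and, with let-7e, complex I (0.672), complex IV (0.984), lipogenesis (0.672) and microRNA processing (0.688). Turned without the 4 libraries were the endothelial list with let-7d (0.243) and, with let-7e, lipolysis (0.248), adipocyte (0.881) and epididymis and testis (0.56). MicroRNA processing turned with no series term for let-7d (0.19) and by fry for let-7e (0.941). Transcripts with let-7 sites gained a call with let-7e with no series term (0.0236) and without the 4 libraries (0.0335), and microRNA processing with no series term (0.0375). Both lists were called higher in early libraries by camera (adjusted p = 0.0395 and 2.14e-06), or 0.866 and 0.0589 with an estimated correlation. Early libraries occur only in the injected groups. The calls gained with no series term thus cannot be told apart from the series difference. At 12717365 to 28972306 counts the median SE of a log2 fold change was 0.171 to 0.19 in the 3 pairwise comparisons. In the simulations, genes planted at 2-fold were recovered in 56% to 60%. That rate holds for 100 genes planted at 2-fold beside 100 at 4-fold, each gene drawn independently. It need not hold where fewer genes differ: Axin2 with let-7d, at 2.11-fold, had an edgeR adjusted p of 0.46.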

Other observations

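In this part the test of the spread of lipogenesis and the list of nuclear noncoding RNAs were chosen after the result was seen; the tests of splits were planned. Some lists not described above were not called. With let-7d, the enzymes of the citric acid cycle were lower in 18 of 20 (median -0.16, camera adjusted p = 0.0985), subunits of complexes II and III in 14 of 14 (median -0.10, adjusted p = 0.264) and subunits of ATP synthase in 13 of 15 (median -0.07, adjusted p = 0.516), though among late libraries the levels of the last pair of lists differed from control by only -0.0261 (exact p = 0.921) and -0.002 (exact p = 0.992). With let-7e, against the same controls, these lists were lower in 16 of 20 (adjusted p = 0.729), 14 of 14 (adjusted p = 0.455) and 12 of 15 (adjusted p = 0.271), and proteins of the mitochondrial ribosome in 61 of 72 (median -0.07, adjusted p = 0.0586). Genes of hypoxia and glycolysis were lower in 19 of 26 with let-7d (adjusted p = 0.24) and 18 of 26 with let-7e (adjusted p = 0.0586). The thermogenic list, which is measured without Ucp1, was not called with let-7d (median 0.12, adjusted p = 0.516), and its test of let-7e against let-7d gave an adjusted p of 0.123.

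Camera called 9 lists between early and late libraries, against a median of 14 in the other splits, so chance is not excluded for them. Early libraries were lower in erythroid markers (median -0.99, adjusted p = 8.4e-05; 0.866 as the adjusted p with an estimated correlation) and in interferon response genes (median -0.41, adjusted p = 8.4e-05; 0.89 with an estimated correlation). Nuclear noncoding RNAs, a list added after the data were seen, were higher (median 0.29, adjusted p = 4.34e-05; 0.289 as the adjusted p with an estimated correlation), with 3 of 7 called.

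With 0 genes called in each of the 4 comparisons, all 100 of 100 splits reach that count of necessity, and the test of splits decides nothing there. Counts at an unadjusted p under 0.05 were reached in 38, 27, 10 and 16 of 100 splits for let-7d, let-7e, let-7e against let-7d and the mean, so chance is not excluded for those. The highest of the other splits called 108 genes for let-7d, 43 for let-7e, 0 for let-7e against let-7d and 824 for the mean. A split that calls so many genes points to a structure of the samples. Of the 297 other splits of the 3 comparisons with the controls, 5 called over 10 genes, and all 5 put control 2 apart from controls 1, 3 and 6, as 34 of the 297 do. That rule, which leaves out control 4, was set after these splits were seen, so it cannot test the place of control 2. The split with 824 calls set controls 1, 3 and 6 together with let-7d 5 and let-7e 4, which with control 4 are the libraries with Lep at or below 801.7 CPM. No label explains this structure. A mislabelled sample, such as control 2, was not tested and stays open, and it would bear on every comparison with the controls.

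The lipogenesis level varied more among controls (SD 0.925) than among late injected libraries (SD 0.262), a ratio of 3.53. A wider spread among controls than among let-7 libraries is a hypothesis from these data. The late SD was 0.127 within let-7d (mean 9.51) and 0.188 within let-7e (mean 9.11). The permutation pooled these 2 groups and did not centre the levels of any group, so its p mixes differences in level with spread. For lipogenesis the exact permutation p was 0.0637, and 0.761 adjusted over 40 lists. The hypothesis thus cannot be told apart from chance with 5 controls, 2 of which (controls 1 and 4) hold the highest Fasn. The imprinted list, with a ratio of 3.51, had an exact p of 0.0171 (0.342 adjusted). The smallest exact p of the 40 lists, 0.00622 (0.249 adjusted), went the other way. It was that of mesothelial markers, with an SD of 0.302 among controls and 1.09 among late injected libraries.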
